A study of Mus musculus with 19 samples.

How the data were processed

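CBFA2T2 ChIP-seq had been performed in NE-4C cells without H3f3a that expressed HA-tagged H3.3WT or H3.3K27M, 1 library per genotype. Groups were taken from the genotype and antibody in the labels, which describe 19 samples in all, and 2 of these had peak lists that were used here. The other ChIP and input libraries were not analysed here. Reads had been trimmed with Trim Galore and peaks called with MACS2 on the mouse build mm10, per the submitters' processing notes, which give no versions. The aligner, duplicate handling and caller settings were not given in the sources used here. Each list was called from 1 ChIP library against an input, as the deposited peak names state, so no replicates were pooled.

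Each peak of the deposited lists carries a position, a summit and 4 values made by the authors' peak caller. Their score column equals 10 times −log10 q cut to a whole number in the deposited files and was not used further. The fold enrichment, a ratio of the ChIP signal at the summit over the local background estimated with the input, was used as deposited to rank and filter peaks within a list. The −log10 p and −log10 q of each peak were used as deposited in the same way. The smallest −log10 q was 1.33 in the H3.3WT list and 1.31 in the H3.3K27M list, the level of a q of 0.05, so weaker sites were removed before deposit. A site near that threshold can appear in one list and be missing from the other at nearly the same enrichment. Neither read counts nor coverage accompany the peaks, so depth is unknown, and a library with more reads or a better precipitation yields more peaks and lower folds at the weakest of them. For that reason fold values of the lists are printed side by side and not divided into a change between genotypes. A ratio is given only at Cbfa2t2 and its pseudogene, to rank these peaks among other shared peaks.

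Coordinates are 1-based on mm10. Gene spans came from the RefSeq annotation of GRCm38.p6, the same assembly, which as used here gives start, end and type of each gene but neither strand, exons nor transcript starts. All peaks lay on chromosomes 1 to 19, X and Y. Because no strand was given, the planned promoter window was replaced by a gene boundary, a summit within 1 kb of either annotated end of a protein-coding gene. Peaks elsewhere were divided into those inside a protein-coding gene and intergenic ones, without a division into exons and introns. The planned motif comparisons and the planned matching of random genes on CpG content need a genome sequence, which was not used here. Random gene lists were matched on the decile of gene length in their place. This substitution was chosen after the files were seen.

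Peaks of the 2 lists were called shared if they overlapped by at least 1 bp. Shares are given with 95% Wilson intervals, which cover counting error only. As a background, each list was placed at random within its chromosomes 1000 times. A gene counted as marked if it had a boundary peak, and the peak with the highest −log10 q represented it. For 28 gene lists, 23 of named symbols and 5 defined by symbol patterns, fixed before the data were examined, members with a boundary peak were compared with all other protein-coding genes by a two-sided Fisher exact test. All 710 listed symbols were found in the annotation. A histocompatibility gene that matched the histone pattern was left out. Benjamini-Hochberg adjustment covered the 56 tests of both peak lists, and a list was called at an adjusted p of at most 0.05. Genes are not replicates, so these p-values describe single libraries and not the genotypes. The excess of genes marked in H3.3K27M alone over those in H3.3WT alone was compared with 10000 random gene lists per list, and an excess outside the middle 95% of random lists was counted as standing apart.

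Named genes followed a rule fixed before the data were examined, applied to gene boundaries in place of the planned promoters. It took the 10 genes with the highest fold at a boundary in each list, the 10 genes per list with the highest −log10 q and no peak of the other list within 1 kb, and the 10 shared genes of best summed rank. It added up to 4 members of each gene list with the highest −log10 q, the genes Cbfa2t2, H3f3a, H3f3b, Kdm6a, Kdm6b and Ezh2, and the 5 strongest peaks by fold in each list. Some genes that the rule picked are not reported here. Members of lists marked in a single genotype, the pseudogene Cbfa2t2-ps1, neighbours of named peaks and small RNA genes were named after their values were seen.

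Alternatives were stricter peak thresholds (−log10 q of at least 5, at least 5 fold), the same number of peaks from both lists, removal of the 1% of peaks with the highest fold, other overlap criteria, windows of 500 bp and 3 kb, any part of a peak within 1 kb of a gene end, and marked genes alone as background. Removal of repeat-like peaks (under 3 fold with −log10 q of at least 20), a stricter definition of genes marked in a single list, gene-length matching, and marked genes alone as background for the excess were added after the data were seen. The scripts were tested on simulated data. With 4000 planted shared peaks 4001 were found, and in 20 simulations over 21887 genes a planted list was called 20 times. In as many simulations without a planted list, 6 of 560 list tests were called. Those drew all genes with equal weight, so they do not give the rate of false calls in the real peak lists. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.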

Results

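Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out in NE-4C, a p53-deficient mouse neural stem cell line. The cells had lost H3f3a, a gene for the histone variant H3.3. They carried an HA-tagged H3.3, either wild-type (H3.3WT) or with methionine in place of lysine 27 (H3.3K27M), the substitution known from childhood diffuse midline glioma. A derivative of the H3.3WT cells also lacked Cbfa2t2, which codes for a corepressor of the MTG (ETO) family. The series listed 19 libraries from these 3 genotypes, 11 of ChIP and 8 of input, with at most 1 ChIP library for any antibody and genotype. Values came from 2 of them, the CBFA2T2 ChIP of H3.3WT cells with 6920 peaks and that of H3.3K27M cells with 8272 peaks. The CBFA2T2 ChIP of the Cbfa2t2 knockout, the inputs and the HA, H3K4me3 and H3K27me3 libraries were not analysed here. Peaks of the 2 lists are set side by side below as a description of 2 libraries. There was no replicate, so no difference between the genotypes could be tested. Read counts were not given with the peaks, so the depth of both libraries is unknown.

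The first question was where the antibody recovered the genes that the design manipulates. No peak lay within 5 kb of H3f3a (chromosome 1, 180802560 to 180813605) in either list. The cells had lost this gene, so the lack of a peak does not show whether CBFA2T2 would bind its intact form. H3f3b, the other gene for H3.3, held an internal peak with a fold of 5.998 in H3.3WT and 3.77 in H3.3K27M. A stronger peak at 44.95 and 36.8 fold lay 4160 and 4155 bp outside H3f3b, more than 1 kb from the end of any protein-coding gene. Inside Cbfa2t2 itself (chromosome 2, 154436098 to 154539356) both lists held 2 peaks. The stronger one spanned 154534874 to 154535190 in H3.3WT, with a fold of 15.9, and 154534872 to 154535198 in H3.3K27M, with a fold of 31.1. The other one, at 154465955 to 154466459 in H3.3WT and 154465949 to 154466383 in H3.3K27M, had folds of 9.12 and 13.3. A pseudogene of the target, Cbfa2t2-ps1 (chromosome 5, 60231378 to 60232203), was covered by a peak of 23.0 fold in H3.3WT and 44.9 fold in H3.3K27M. Edges of the strong Cbfa2t2 peak differed between the lists by 10 bp in sum and those of the pseudogene peak by 1 bp, against a median of 114 bp over 515 strong shared peaks. The map of peaks at Cbfa2t2 and its pseudogene shows these intervals.

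**Figure D1:**
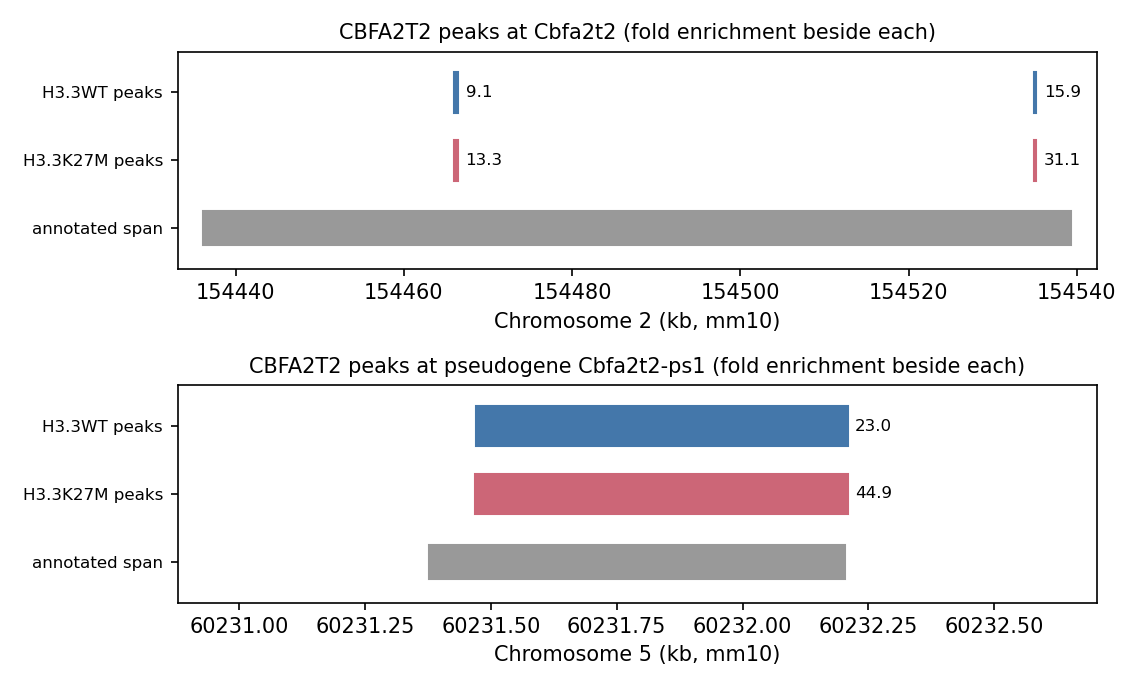
Positions of CBFA2T2 peaks along Cbfa2t2 (upper panel) and its pseudogene Cbfa2t2-ps1 (lower panel), with the coordinate on mm10 in kb on the horizontal axis. Blue bars are H3.3WT peaks, red bars H3.3K27M peaks and grey bars the annotated span, and the number beside each peak is its fold enrichment, 15.9 and 31.1 at the stronger Cbfa2t2 peak and 23.0 and 44.9 at the pseudogene.

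Among genes for H3K27 demethylases and methyltransferases, Kdm6b had 7 peaks within 5 kb in each list. Most of them were of moderate height, up to 9.44 fold in H3.3WT and 9.06 fold in H3.3K27M inside the gene. The highest of the 7, at 26.6 and 24.3 fold, lay at the ends of its neighbours Cyb5d1, Naa38 and Tmem88. Kdm6a, the X-linked H3K27 demethylase gene, held 1 internal peak at 5.96 and 5.49 fold. Ezh2, the catalytic subunit of Polycomb repressive complex PRC2, had 1 peak at a boundary, weak in both lists at 3.24 fold (−log10 q of 1.53) in H3.3WT and 4.28 fold (−log10 q of 4.66) in H3.3K27M. Fold and −log10 q are the values of the authors' peak caller within each list and carry no replicate error.

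The second question was how far H3.3WT and H3.3K27M cells shared CBFA2T2 sites. The strongest sites by fold were largely common to both lists. The highest peak of both lay between Fyco1, an adaptor of autophagosome transport, and the chemokine receptor gene Xcr1 (chromosome 9, 123851564 to 123852447 in H3.3WT), with folds of 108 in H3.3WT and 85.5 in H3.3K27M. The shared boundary of the deubiquitinase gene Usp5 and Cdca3 followed in H3.3WT with 88.9 fold and had 75.1 fold in H3.3K27M. Gsk3a, a kinase gene of glycogen and Wnt signalling, had 86.6 and 57.6 fold, and Prcc had 64.8 and 72.9 fold. Further sites of high rank in both lists lay at Chchd4 and Tmem43 (58.3 and 60.7 fold) and at Mmachc and Ccdc163 (56.5 and 62.2 fold). Chchd4 serves protein import into mitochondria and Mmachc acts on cobalamin. The fourth highest H3.3WT peak lay at the uncharacterised 9430015G10Rik (70.2 and 49.0 fold). Pfdn6 and Wdr46 (61.6 and 41.7 fold) and the DNA repair gene Brca1 (61.4 and 35.9 fold) completed its leading genes. In H3.3K27M the second highest peak lay at Sharpin and Maf1, the latter a repressor of RNA polymerase III, with 84.7 fold against 37.9 fold in the H3.3WT list. Hyal3 and Ifrd2 had 64.7 fold in H3.3K27M and 24.1 fold in H3.3WT.

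Of the 6920 H3.3WT peaks, 5496 overlapped an H3.3K27M peak by at least 1 bp, which is 79.4% (95% Wilson interval 78.5 to 80.4%). Of the 8272 H3.3K27M peaks, 5486 overlapped an H3.3WT peak, which is 66.3% (65.3 to 67.3%). Peaks placed at random on the same chromosomes overlapped in 0.406% and 0.343% of cases on average. Sharing rose with the strength of a peak. In the lowest quartile by −log10 q, 51.7% of H3.3WT peaks and 31.6% of H3.3K27M peaks were shared, and in the highest quartile 99.5% and 98.8%. The 1424 unshared H3.3WT peaks had a median fold of 4.91 against 6.82 for shared ones, and the 2786 unshared H3.3K27M peaks had 4.59 against 6.68. The intervals cover counting error over peaks, which are not independent replicates.

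**Figure D2:**
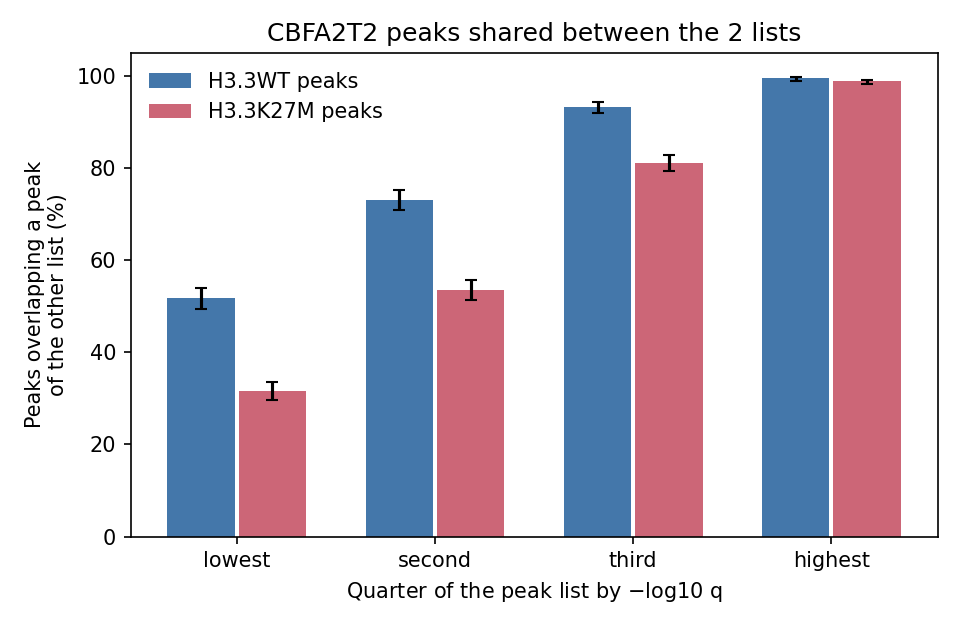
Share of peaks that overlap a peak of the other list (vertical axis, %) by quartile of the own list ranked on −log10 q (horizontal axis), for H3.3WT (blue) and H3.3K27M (red), 1 library each, with 95% Wilson intervals as error bars. The share runs from 51.7% to 99.5% in H3.3WT and from 31.6% to 98.8% in H3.3K27M.

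CBFA2T2 peaks lay mostly at the ends of protein-coding genes. A summit within 1 kb of an annotated gene end was found for 65.7% of H3.3WT peaks (64.6 to 66.8%) and 64.5% of H3.3K27M peaks (63.5 to 65.6%), against 3.26% of randomly placed peaks for both lists. Gene interiors held 17.8% and 19.03% of peaks where placement gave 39.4% and 39.5%, and intergenic sequence held 16.5% and 16.4% where placement gave 57.3%. Shared peaks lay at a gene boundary in 72.9% (H3.3WT) and 72.7% (H3.3K27M) of cases. Among unshared peaks the share was 38.1% (35.6 to 40.6%) in H3.3WT and 48.5% (46.7 to 50.4%) in H3.3K27M. Most genes over 4 kb had their peak at a single end: 2.41% in H3.3WT and 2.77% in H3.3K27M had peaks at both ends. The annotation used here gave no strand, so a boundary peak is not assigned to the start or the finish of transcription.

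Boundary peaks marked 5427 of 21887 protein-coding genes in H3.3WT (24.8%) and 6256 in H3.3K27M (28.6%). Of these, 4857 genes had one in both lists, where lists of this size drawn independently would share 1551. A further 570 genes had one in the H3.3WT list and not in the other, and 1399 in the H3.3K27M list and not in the other. This imbalance depended on the peaks kept: the counts were 829 and 931 with the same number of peaks from both lists, 844 and 923 with peaks of at least 5 fold, and 482 and 1166 at −log10 q of at least 5. The strongest of the H3.3K27M set by −log10 q, with no H3.3WT peak within 1 kb, were Nagpa (14.6 fold), a gene of lysosomal enzyme targeting, the guanylate kinase gene Guk1 (11.7 fold), Rmnd5b, Pelp1, the autophagy gene Epg5 (11.3 fold), Zfp174, Frmpd1, Inpp5b and Morn4. The tenth was Runx1t1 (7.29 fold, −log10 q of 20.6), a paralogue of Cbfa2t2. The single H3.3WT peak within 5 kb of Runx1t1 lay at 13750546 to 13751375 on chromosome 4 with 4.43 fold, inside the gene. On the H3.3WT side the strongest were Trmt10b (13.7 fold), Tsc1 (8.07 fold), an inhibitor of the mTORC1 pathway, the mitochondrial translation factor gene Tsfm (12.1 fold), the replication gene Gins1 (9.38 fold), Shq1, Arfgap1, Cbwd1, Psmb4 and Car11. Ier5l (8.84 fold) ranked among them by its H3.3WT peak, but more than 1 kb from that peak it also had a boundary peak of 3.67 fold in H3.3K27M. The −log10 q of these genes ran from 15.5 to 23.3 in H3.3WT and from 20.6 to 32.9 in H3.3K27M. The leading genes, Trmt10b in H3.3WT and Nagpa in H3.3K27M, stood at the 77.9 and 84.5 percentiles of −log10 q in their lists. In H3.3WT only Trmt10b lay in the highest quartile of its list by −log10 q. In H3.3K27M all of the named genes except Runx1t1 did.

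The third question, from the subject of the series, was whether CBFA2T2 sites lay at metabolic genes. Genes of oxidative phosphorylation carried boundary peaks at 33 of 39 members in H3.3WT and 31 of 39 in H3.3K27M, among them Ndufb5 of respiratory complex I (28.8 and 38.3 fold), Atp5o of ATP synthase (22.7 and 33.3 fold) and Cox7c of cytochrome c oxidase (19.6 and 18.7 fold). Odds ratios against all other protein-coding genes were 16.8 (95% interval 6.94 to 49.0; adjusted exact p = 3.09e-14) and 9.72 (4.37 to 24.5; adjusted exact p = 2.85e-10). In the TCA cycle and α-ketoglutarate list, 23 and 27 of 41 genes had a peak, among them Suclg1 (22.1 and 28.7 fold), Mdh1 (10.6 and 14.4 fold) and Bcat2 (14.8 and 10.5 fold). Its odds ratios were 3.89 (2.01 to 7.65; adjusted exact p = 8.73e-05) and 4.83 (2.45 to 9.98; adjusted exact p = 3.41e-06). The other genes include silent families such as olfactory receptors, so the odds ratios do not tell metabolic genes from active genes in general. The amino acid response list of Atf4 targets had 15 and 20 of 31 members with a peak (adjusted exact p = 0.0116 and 0.000107), led by the tRNA synthetase genes Aars (9.86 and 13.4 fold) and Wars (9.73 and 11.96 fold), Atf4 itself (22.1 and 11.7 fold) and Chac1 (3.97 and 11.2 fold). For H3.3WT the call on this list ended with peaks of −log10 q of at least 5 and with peaks of at least 5 fold.

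Other metabolic lists did not pass the threshold in either peak list. Glycolysis had 9 and 12 of 28 genes, with Gapdh at 7.77 and 12.7 fold and Pkm at 4.09 and 4.199 fold. Serine, one-carbon and methionine metabolism had 13 and 12 of 31, with Psph at 13.5 and 11.5 fold. Cholesterol and fatty acid synthesis had 14 of 36 in both, including Fdps at 16.3 and 10.5 fold. Nucleotide synthesis had 11 and 12 of 29, with the ribonucleotide reductase gene Rrm1 at 23.3 and 15.5 fold. Their adjusted exact p ranged from 0.0592 to 0.446.

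Outside metabolism, ribosomal protein genes were the most often marked of all 28 lists. Of 77 members, 69 had a boundary peak in each peak list, the identical 69 in both, led by Rps27a (37.7 and 42.5 fold), Rpl34 (31.3 and 34.7 fold), Rpl9 and Rps12. Their odds ratios were 26.5 (12.7 to 63.8; adjusted exact p = 3.01e-32) and 21.8 (10.4 to 52.5; adjusted exact p = 3.23e-28). Canonical histone genes had 53 and 56 of 70 members near a peak (odds ratios of 9.54 and 10.1; adjusted exact p = 3.78e-18 and 4.06e-18). These genes stand close together, and their members were reached by 37 peaks in H3.3WT and 42 in H3.3K27M. Examples are H2ac19 and H3c15, which shared a peak of 7.90 and 11.4 fold. Zinc finger genes of the Zfp series had 172 and 196 of 397 (odds ratios of 2.36 and 2.48; adjusted exact p = 2.70e-15 and 8.87e-18), among them Zfp189 at 22.5 and 44.0 fold and Zfp384 at 31.2 and 32.7 fold.

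Chromatin regulators were marked more often than all other genes, silent families included, in several lists. Among Polycomb and H3K27 methylation genes, 16 and 21 of 33 had a peak (adjusted exact p = 0.00861 and 0.000131), including Asxl1 (11.4 and 14.8 fold) and Bap1 (10.2 and 15.9 fold) of the H2A deubiquitinase and the Polycomb group gene Pcgf2 (14.5 and 8.49 fold). Of the demethylases and hydroxylases that use 2-oxoglutarate, 15 and 20 of 28 had a peak (adjusted exact p = 0.00330 and 1.29e-05), led by the RNA demethylase gene Fto (32.4 and 16.6 fold), the H3K4 demethylase gene Kdm5a (18.0 and 8.70 fold) and Jmjd6. Histone H3.3 genes and chaperones had 6 and 9 of 14, past the threshold for H3.3K27M alone (adjusted exact p = 0.0121 against 0.176), with Daxx at 9.81 and 13.4 fold. MTG family and corepressor partners had 10 and 14 of 32 (adjusted exact p = 0.472 and 0.115), with Gps2 of the NCoR complex at 17.8 and 13.8 fold. With peaks of at least 5 fold, the calls ended for Polycomb genes in H3.3WT and for the 2-oxoglutarate list and the H3.3 list in H3.3K27M. The H3.3 call also ended at −log10 q of at least 5 and with equal list lengths.

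**Figure D3:**
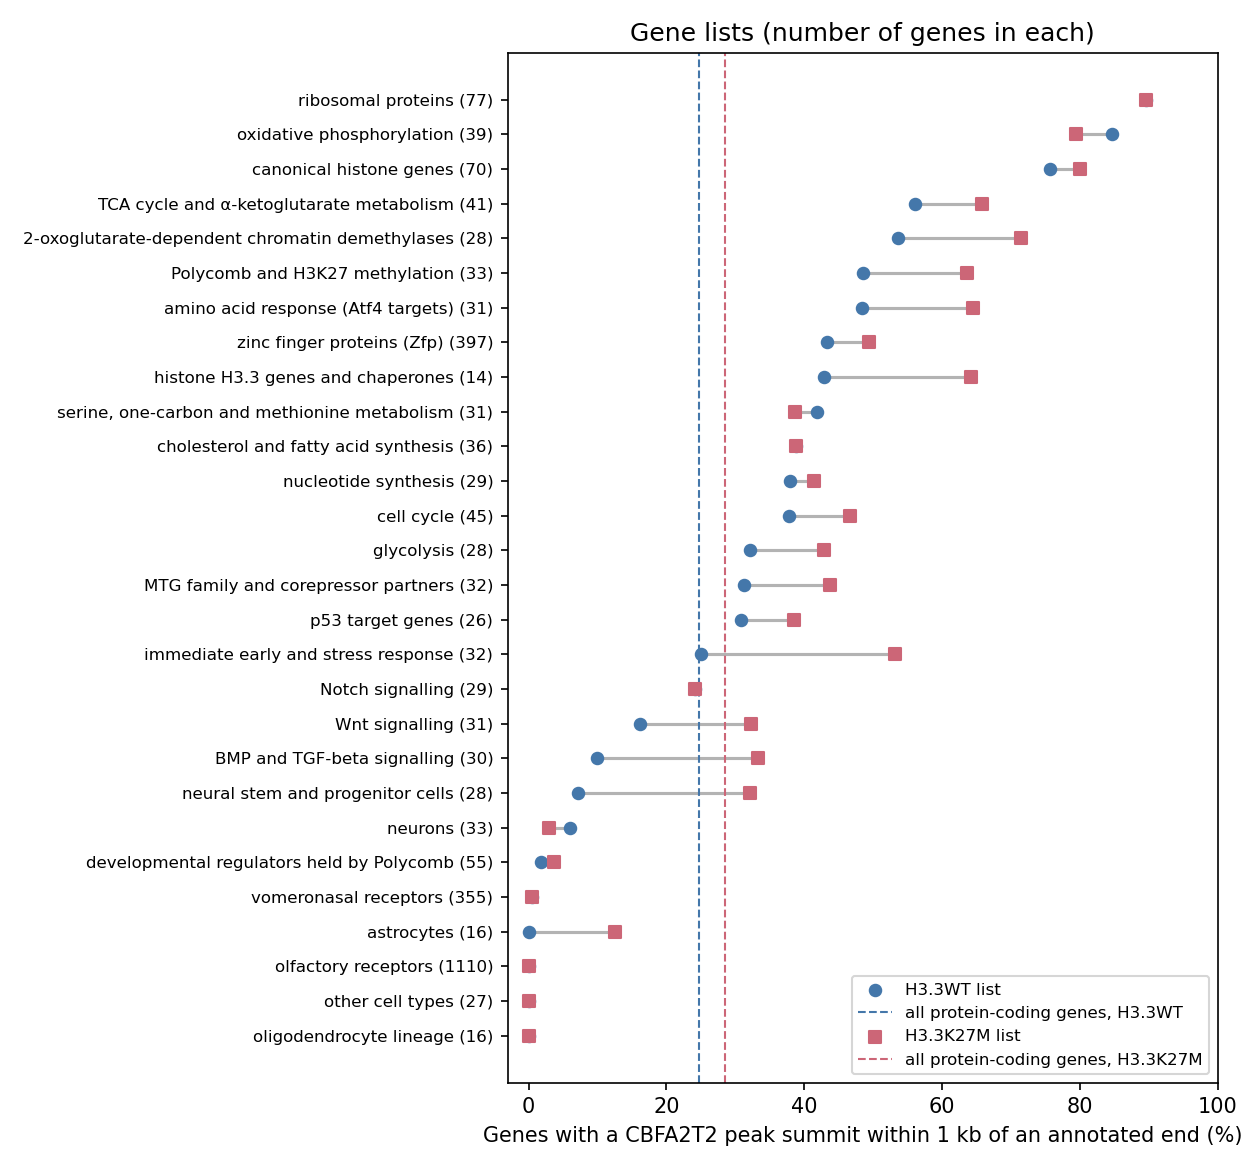
Share of the genes of each list with a CBFA2T2 peak summit within 1 kb of an annotated end (horizontal axis, %), for the H3.3WT list (blue circles) and the H3.3K27M list (red squares, drawn on top where both are equal), with the number of genes in parentheses. Dashed lines give the share of all protein-coding genes, 24.8% and 28.6%; ribosomal proteins lie highest at 69 of 77 genes, and olfactory receptors, other cell types and oligodendrocyte genes lie at 0.

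Genes of differentiated cells and silent gene families were largely free of boundary peaks. No olfactory receptor gene of 1110 had one in either list (adjusted exact p = 1.07e-140 and 2.88e-166), and 2 of 355 vomeronasal receptor genes did in both, Vmn2r29 and Vmn1r4. Developmental regulators held by Polycomb had 1 of 55 in H3.3WT, Foxf1 (5.43 fold), and 2 in H3.3K27M, Six2 (4.33 fold) and Dlx2 (4.14 fold), with adjusted exact p = 1.80e-05 and 1.30e-05. Markers of neurons had 2 of 33 in H3.3WT, Eomes and Gap43, and 1 in H3.3K27M, Insm1 (adjusted exact p = 0.0168 and 0.000894). Oligodendrocyte genes had 0 of 16 in both lists (adjusted exact p = 0.0306 and 0.0182). Genes of muscle, blood, liver, gut, endothelium and microglia had 0 of 27 in both (adjusted exact p = 0.00152 and 0.000439). Astrocyte genes had 0 of 16 in H3.3WT (adjusted exact p = 0.0306) and 2 in H3.3K27M, Nfib and Glul (adjusted exact p = 0.330). With peaks of at least 5 fold, the calls ended on the neuron and astrocyte lists in H3.3WT and on the oligodendrocyte list in both. The astrocyte and oligodendrocyte calls in H3.3WT also ended at −log10 q of at least 5 and with a 500 bp window, and a window of 3 kb ended the H3.3K27M calls on neurons and oligodendrocytes.

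Signalling and proliferation lists stood nearer to the average gene. Cell cycle genes had 17 and 21 of 45 (adjusted exact p = 0.0867 and 0.0225), with the spindle checkpoint gene Bub1b at 11.1 and 21.1 fold and the replication gene Mcm3 at 8.62 and 10.6 fold. Notch signalling had 7 of 29 in both lists, including Rfng, and Wnt signalling 5 and 10 of 31, including Dvl2 (16.7 and 17.3 fold). Targets of p53 had 8 and 10 of 26, including Sesn1 (15.1 and 7.81 fold) and Bax (9.38 and 13.8 fold). No call was made on the Notch, Wnt or p53 list (adjusted exact p from 0.3404 to 1).

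Many lists had more members marked in H3.3K27M than in H3.3WT, as had protein-coding genes as a whole (28.6% against 24.8%). The immediate early and stress response list had 8 of 32 genes marked in H3.3WT (adjusted exact p = 1) and 17 in H3.3K27M (adjusted exact p = 0.0111). Fosl2 (7.42 fold), Nr4a2 (6.51 fold), Junb (5.95 fold), Gadd45g (5.65 fold), Dusp6, Fosb, Btg2, Jund, Klf4 and Ier2 had a boundary peak in the H3.3K27M list alone, and Klf2 in the H3.3WT list alone. The Ier2 peak stood at the calling threshold, with −log10 q of 1.31. Fos was marked in both, at 8.08 and 9.62 fold. Neural stem and progenitor genes had 2 and 9 of 28 (adjusted exact p = 0.0474, below other genes, and 0.717), with Fgfr1 (5.82 fold), Id1 (5.75 fold), the intermediate filament genes Nes (5.24 fold) and Vim (3.82 fold), Cdh2, Hes1 and Msi2 in the H3.3K27M list alone. BMP and TGF-beta signalling had 3 and 10 of 30 (adjusted exact p = 0.128 and 0.602), those in the H3.3K27M list alone being Smad4 (7.04 fold), Id1, Acvr2a, Ski, Smad6, Smad2 and Bmpr2. In the Atf4 list Ddit4 (6.37 fold), Trib3 (5.73 fold), Cebpb, Asns, Sesn2 and Vldlr were marked in H3.3K27M alone and Psat1 in H3.3WT alone. The H3.3K27M call on immediate early genes ended at −log10 q of at least 5, at 5 fold and with equal list lengths, and the H3.3WT call on neural stem genes under these, under the other windows and without the 1% of peaks with the highest fold.

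Genes marked in either list served as a further background. It leaves out all genes without a boundary peak, so it compares lists only among genes already marked and does not measure enrichment near peaks. Of the 33 calls, 4 were also made there, 16 were not, and 13 could not be tested because fewer than 5 members were marked, as for olfactory receptors. Odds ratios for this background were computed with a small constant added to every count, unlike those above. Those kept were ribosomal proteins in both lists (odds ratios of 36.3 and 12.8), oxidative phosphorylation in H3.3WT (17.4, against 1.15 in H3.3K27M) and neural stem genes in H3.3WT (0.0856). All 69 marked ribosomal protein genes had a peak in both lists. Of 33 marked oxidative phosphorylation genes, all had one in H3.3WT and 31 in H3.3K27M. Where all marked members had a peak, the constant sets the size of the ratio. BMP and immediate early genes were called in H3.3WT there alone, below other marked genes (0.120 and 0.208). Odds ratios without a call were 0.932 and 1.004 for the TCA cycle list, 0.614 and 1.25 for both Atf4 targets and 2-oxoglutarate enzymes, 0.773 and 3.93 for Polycomb genes, 1.85 and 1.15 for canonical histones and 0.859 and 0.641 for Zfp genes. In H3.3K27M they were 1.74 for the H3.3 list, 0.559 for cell cycle and 1.06 for immediate early genes. All marked Polycomb genes and all marked genes of the H3.3 list had a peak in H3.3K27M, so 3.93 and 1.74 also rest on the constant.

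The excess of genes marked in H3.3K27M alone over those marked in H3.3WT alone was set against 10000 random gene lists of the same size and gene length. It stood at the 100th percentile for immediate early genes (excess of 9), at 99.97 for neural stem genes (7), at 99.75 for BMP and TGF-beta signalling (7) and at 98.3 for Atf4 targets (5). Ribosomal proteins had an excess of 0 and oxidative phosphorylation genes one of −2, at the 21.1 and 3.60 percentiles. Olfactory receptors, with no marked gene in either list, lay at the 0.3 percentile. Under the main setting the remaining lists lay within the middle 95% of random lists, among them 2-oxoglutarate enzymes at 97.1, Wnt signalling at 97.1 and Polycomb genes at 96.3. These percentiles describe 2 libraries and are no test of genotype. Peaks of −log10 q of at least 5 left the neural stem and BMP lists at 92.0 and 85.9, and the same number of peaks in both lists left Atf4 targets at 95.9. Peaks of at least 5 fold left these 3 lists at 89.1, 85.1 and 95.9, with immediate early genes at 99.3. Other lists left the middle 95% under such settings. Cell cycle genes stood at 99.7 with peaks of −log10 q of at least 5 and at 99.8 with peaks of at least 5 fold, and Zfp genes at 99.8 with the former. At 5 fold Polycomb genes stood at 98.3 and Wnt signalling at 98.5 on the high side, and 2-oxoglutarate enzymes at 2.41 and oxidative phosphorylation at 0.39 on the low side. Without the 1% of peaks with the highest fold, 2-oxoglutarate enzymes stood at 99.0 and oxidative phosphorylation at 0.245. Canonical histones fell to the 0 percentile with equal list lengths and rose to 99.9 with a window of 3 kb, where TCA cycle genes stood at 98.8.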

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

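No read counts were given, so depth limits these comparisons by an unknown amount, and 1 library per genotype leaves no library to omit. No paired analysis was possible because each group holds 1 library. Motif comparisons and CpG matching were not run. The gene boundary, on which the gene counts, list comparisons and windows rest, replaced the planned promoter window. All other settings were fixed before the data were examined except the removal of repeat-like peaks, gene-length matching, the stricter definition of genes marked in a single list and marked genes as background for the excess.

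Shared H3.3WT peaks (79.4% in the report) came to 81.9% at −log10 q of at least 5, 70.5% at 5 fold, 74.2% with equal list lengths, 76.7% with 50% of the peak covered, 71.8% with reciprocal cover, 75.2% by summits and 80.7% within 1 kb. By quartile from the lowest −log10 q they came to 51.7%, 73.1%, 93.4% and 99.5%. Shared H3.3K27M peaks (66.3%) came to 68.9%, 68.6%, 73.9%, 61.4%, 60.1%, 62.9% and 67.7% under the same settings in that order, and to 31.6%, 53.6%, 81.2% and 98.8% by quartile. With equal list lengths both shares have the same number of peaks as denominator, so they are nearly equal by construction.

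Boundary peaks of H3.3WT (65.7%) came to 69.0% at −log10 q of at least 5, 68.6% at 5 fold, 61.0% with a window of 500 bp and 72.8% with 3 kb. Those of H3.3K27M (64.5%) came to 68.2%, 68.6%, 59.4% and 72.4%, and to 67.0% with equal lengths. The window results follow from its width, and the cause of the others was not tested. Counts of genes marked in H3.3WT, in H3.3K27M and in both stayed within 1.5 times of those in the report under every setting run. Genes marked in H3.3K27M alone did not, falling from 1399 to 931 with equal lengths and 923 at 5 fold, where those in H3.3WT alone rose from 570 to 829 and 844.

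With marked genes alone as background 6 lists were called, 4 of the 33 calls in the report and 2 new ones, BMP and immediate early genes in H3.3WT. Another 13 calls could not be tested there. The over-represented lists then numbered 2 (H3.3WT) and 1 (H3.3K27M) and the under-represented ones 3 and 0, against 8, 11, 8 and 6. In that smaller background 8 odds ratios of lists called with either background turned below 1. For H3.3WT these were TCA cycle 0.932, Atf4 targets 0.614, Polycomb genes 0.773, 2-oxoglutarate enzymes 0.614, immediate early genes 0.208 and Zfp genes 0.859, and for H3.3K27M cell cycle 0.559 and Zfp genes 0.641. Genes without a peak are left out of that background, so it does not measure enrichment near peaks. Under-represented lists in H3.3WT numbered 5 at −log10 q of at least 5, 4 at 5 fold and 5 with 500 bp. The cause was not tested.

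The number of lists with an excess outside the middle 95% of random lists rose from 5 to 9 with a window of 3 kb, and the cause was not tested. Olfactory receptors turned to the 75.2 percentile at 5 fold and 75.3 with equal lengths. No olfactory receptor was marked, so their percentile only mirrors the random lists. Over single lists, 471 values under planned settings and 102 under added ones kept their side of the threshold, 35 were no longer past it and 7 came to be past it, while 23 and 3 list percentiles crossed into or out of the middle 95%.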

Other observations

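Genes of tRNAs and small nuclear RNAs were also near CBFA2T2 peaks, a group chosen after the data were seen. Of 408 tRNA genes, 46 had a summit within 250 bp in H3.3WT (11.3%, 95% Wilson interval 8.56 to 14.7%) and 72 in H3.3K27M (17.6%, 14.3 to 21.6%), where random placement gave means of 0.639 and 0.769 genes. Both lists marked 29 of them, H3.3K27M alone 43 and H3.3WT alone 17. With the same number of peaks in both lists the H3.3K27M count was 51. Of the 359 tRNA genes away from the ends of protein-coding genes, 31 and 59 were marked. Small nuclear RNA genes had 42 and 43 of 1004 marked, 41 of them in both lists, and 35 and 37 of the 971 away from the ends of coding genes. Among single RNA genes, Rpph1 of RNase P had a peak of 5.53 fold in H3.3WT and 9.05 in H3.3K27M, Rmrp of RNase MRP 4.199 and 5.13, and Rnu7, the U7 RNA gene, 6.13 and 11.1. Rn7sk had a peak in the H3.3K27M list alone (4.49 fold), and Terc had none in either. Small nucleolar RNA genes had 8 and 6 of 1340 marked, where placement gave means of 2.34 and 2.71 genes. Only 3 and 2 of these lay away from the ends of protein-coding genes, within the range of placement. MicroRNA genes had 25 and 31 of 1228 marked, but 6 and 8 away from such ends, where placement on all microRNA genes gave at most 8 and 11.

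Some of the peaks with the highest −log10 q were of another kind. In H3.3WT the leading value, 4913, belonged to a peak on chromosome 2 at 98666629 to 98667277 with a fold of 2.42, 1035177 bp from the nearest protein-coding gene, Lrrc4c. Peaks of under 3 fold with −log10 q of at least 20 numbered 27 in H3.3WT and 22 in H3.3K27M, and 18 and 15 of them lay on chromosome 9 between 3000256 and 3038250.

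All tests of the patterns weighed next were chosen after the data were seen. The first pattern is the larger number of Atf4 target, neural stem, immediate early and BMP genes marked in H3.3K27M, 29 of 116 genes in that list alone against 2 in H3.3WT alone. The 4 lists were picked for this excess, so it was ranked, in SD over its expectation, among 10000 permutations of genes within length deciles, in each of which the 4 lists of highest percentile were picked again. The longer H3.3K27M list is argued against as the whole cause. With equal lengths the counts were 21 and 5, at the 99.83 percentile of such picks. With peaks of at least 5 fold they were 16 and 6, a setting not ranked among such picks. At −log10 q of at least 5 they were 21 and 3, at the 99.92 percentile. This cannot decide on peaks near the calling threshold, because a higher cut only moves the threshold. For example, Chac1, Ddit3 and Bmp7 were marked in both lists before that cut. Their H3.3WT peaks, with −log10 q of 4.01, 4.55 and 4.18, fell below it. Displaced summits of overlapping peaks are argued against, since 0% of the 29 genes had a boundary peak that overlapped an H3.3WT peak. Such overlap was also missing for 1383 of all 1399 genes marked in H3.3K27M alone, so this is not particular to the 4 lists. Adjacent peaks without overlap are not covered, but with a window of 3 kb the counts were 28 and 3. Peaks near the calling threshold stay open for all 4 lists. The neural stem and BMP lists stood at 92.0 and 85.9 one by one at −log10 q of at least 5. A difference in precipitation or depth between the libraries and an effect of H3.3K27M also stay open and untested, with 1 library per genotype.

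The second pattern is the concentration of peaks at the ends of housekeeping genes, which 69 of 77 ribosomal protein genes had in both lists. A candidate explanation is signal that any precipitation gives at open, active promoters. Its test is the CBFA2T2 ChIP of Cbfa2t2 knockout cells, not analysed here, so it cannot be told apart from CBFA2T2 binding. Signal that follows transcript level alone cannot be told apart either, since transcripts were not measured here. Ribosomal protein genes held at most 2 of the 100 boundary genes of highest fold, where their number among marked genes gives 1.27 and 1.10, but their median fold lay at the 78.0 and 82.0 percentiles of peaks against 58.8 and 58.9 for all marked genes.

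The third pattern is the pair of strong peaks in Cbfa2t2 and Cbfa2t2-ps1. The pseudogene peak was higher by 1.44 times or more in both lists. Fold is a ratio over the local background of each site, so this does not show where the reads came from. Reads of a Cbfa2t2 peak placed on the pseudogene therefore stay open. A lowest fold of 15.9 argues against a collapsed repeat like the repeat-like peaks, which had under 3 fold. The −log10 q at the pseudogene was 444 in H3.3WT and 664 in H3.3K27M. Named genes of similar fold had less, such as Hyal3 (24.1 fold, 197) in H3.3WT and Zfp189 (44.0 fold, 272) in H3.3K27M. Fold does not give the height of the input, so extra copies that raised it less stay open. Copies of Cbfa2t2 DNA in the ChIP libraries cannot be told apart from CBFA2T2 binding. The edges of both peaks differed little between lists (1.17 percentile or lower of 515 strong shared peaks), but this raised the explanation and is no test of it. The ratio of H3.3K27M to H3.3WT fold was 1.96 at Cbfa2t2 and 1.95 at the pseudogene, the 98.6 and 98.3 percentiles of these peaks. The Cbfa2t2 peak was among the narrowest, 317 and 327 bp against medians of 767 and 811 bp. The pseudogene peak, at 739 and 740 bp, was not. These values do not tell such copies apart from CBFA2T2 binding either. No biological explanation was tested.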
